A study of Mus musculus with 6 samples.

How the data were processed

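Primary hepatocytes of male C57Bl6 mice were cultured between 2 collagen layers and exposed for 48 hours to 10 µM cyclosporin A or to 0.5% DMSO, the vehicle, per the labels' protocols. The labels describe 3 independent experiments, each from a different animal, and give 3 arrays per condition, 1 array per sample, hybridised with biotin-labelled cRNA prepared by the Affymetrix protocol. Whether the CsA cultures also held 0.5% DMSO is not given in the sources used here, so a difference is between the cultures as labelled. The array type and the version of the probe set definition were not given in the sources used here.

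The deposited values are log2 expression values made with RMA in R 2.11.0, per the submitters' processing notes. RMA corrects the background, makes the arrays' distributions alike and summarises the probes of a probe set on the log2 scale. It therefore removes any change in total RNA per cell and compresses differences of very dim and very bright probe sets. The table held 16331 rows with values from 2.44 to 15.3, no missing value and no control row. Array medians lay between 6.70 and 6.78. The precision was limited by the number of arrays, 3 per group, and no detection call was used here.

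Rows were named through the platform's gene table. It gave 1 symbol to 15136 rows (92.7%) and several symbols to 0 rows. The other 1195 rows are unnamed here and were counted in the tests of all rows only. Symbols were checked by Entrez ID against a RefSeq gene table of assembly GRCm38.p6, which changed 0 of them. No coordinates are given because no genome build is named for the values. The named rows stood for 15133 genes, and for the 3 genes with 2 rows the row with the higher mean over all arrays was used. Members of near-identical families, such as the Cyp3a, Ugt2b, Ces1 and Aldh1a genes and Hspa1a, can share hybridisation. Probe sequences were not used here, so their separate values are uncertain.

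Groups came from the sample titles. CsA was compared with DMSO by a linear model per row with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with no covariate. P-values were adjusted over all 16331 rows by the Benjamini-Hochberg method, and an adjusted p under 0.05 was the threshold. Differences are CsA minus DMSO on the log2 scale with the moderated standard error (SE). A fold is 2 raised to the size of that difference. Counts at a minimum fold used 1.5-fold.

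A total of 34 gene lists, covering liver pathways, stress responses and the markers of other liver and blood cells, were written before the data were examined. They held 1152 symbols, of which 939 were measured and named. Some genes, such as Nr1h4, Nr1i2, Acta2 and Slc40a1, stand in more than 1 list, so shifted lists are not all separate evidence. The 33 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the 33 lists. Camera with a correlation estimated from the arrays, camera on ranks and fry were run as alternatives. Fry asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. For each list the count of changed genes is also given adjusted over the list alone. The genes named in the text followed a rule written before the data were examined. It took the 10 largest differences in each direction among named genes past the threshold whose groups did not overlap, a panel of 15 genes of bile acid transport, drug metabolism and stress, and up to 4 members of each list with the smallest adjusted p. Of the panel, 13 genes are reported and the other 2 were not analysed here.

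Replicate numbers were shared by the groups. Before the fits were compared, the deviations of each array from its group mean were correlated across rows. Same-numbered arrays had correlations of 0.398, 0.242 and 0.499, and each array correlated best with its own number. For DMSO replicate 2 the margin was small, with 0.221 for CsA replicate 1, so the pairing of replicate 2 is the least clear. The titles carry 1 shared prefix for the 3 CsA arrays and 3 different prefixes for the DMSO arrays, which the labels do not explain, so that both groups came from the same 3 animals is an inference. With the labels' 3 animals the correlations were taken as pairing, and a fit with the replicate number as a block was the alternative. It is given beside a result where it changes a call or moves a count by more than 1.5 times. Camera with an estimated correlation, camera on ranks and fry were run without that block. Deviations shared by same-numbered arrays therefore stayed in the estimated correlation.

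Other alternatives fixed before the data were examined were a trended and a robust prior variance, array weights, repeated quantile normalization, centring of the arrays, leaving out the dimmest 20% or 50% of rows, averaging the rows of a gene with the unnamed rows left out, a threshold of 0.01, and leaving out each array in turn. Leaving out both arrays numbered 3 was added after seeing the data. Lists were also set against 10000 random lists matched on mean level in 20 bins.

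The steps were tested on simulated data before use. With 200 of 16331 rows changed in arrays simulated for this comparison, 20% of the rows changed by 0.5 on the log2 scale were recovered, 76% of those changed by 1, and 100% of those changed by 2 or 3. Of 154 rows called there, 6 were false. In simulated arrays with 1 shifted list among the 33, that list was called, as was 1 list sharing genes with it, and 0 unrelated lists. Genes varied independently of each other in these arrays, so the list test was not tried on correlated genes. The 200 changed rows were far fewer than the 3037 called in the data. As the adjusted threshold depends on how many rows change, the recovered shares may not carry over. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.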

Results

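Gene expression was measured on 6 arrays of primary mouse hepatocytes, 3 exposed for 48 hours to 10 µM cyclosporin A (CsA) and 3 to 0.5% DMSO, the vehicle control. Whether the CsA cultures also held DMSO, and whether both groups came from the same 3 animals, is not stated outright in the labels. CsA is an immunosuppressant that binds cyclophilins and inhibits calcineurin, and it is known to impair bile flow. The series addressed the screening of drug-induced liver toxicity in cultured hepatocytes. The table held log2 RMA values for 16331 rows, and array medians lay between 6.70 and 6.78. Correlations over all rows were 0.990 to 0.997 within groups and 0.969 to 0.981 between groups. The first principal component took 69.4% of the variance and separated CsA from DMSO. The second took 17.3% and set both arrays numbered 3 apart from the other 4.

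**Figure D1:**
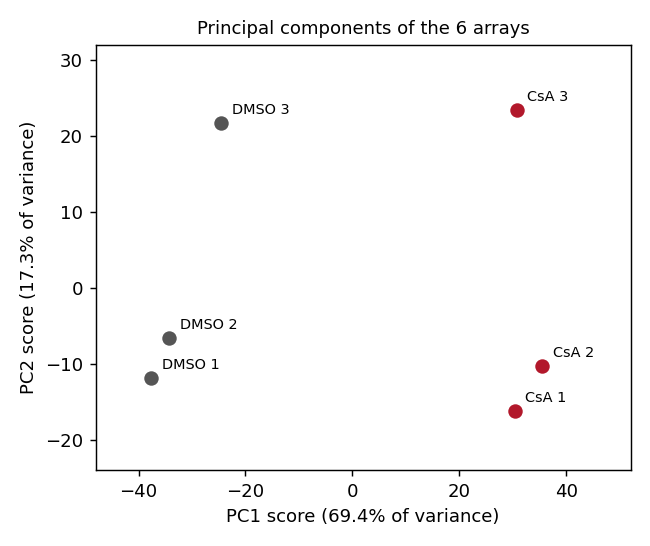
Scores of the 6 arrays on the first principal component (x axis, 69.4% of variance) and the second (y axis, 17.3% of variance), grey for DMSO and red for CsA, with 1 point per array. All CsA arrays lie to the right of all DMSO arrays, and the arrays numbered 3 have the highest scores on the second component, 21.6 and 23.4.

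After CsA, lists of genes of the hepatocyte's own work fell together. They covered cytochrome P450s, conjugating enzymes, bile acid genes, fatty acid oxidation, plasma proteins, the urea cycle with amino acid breakdown, and gluconeogenesis with glycolysis. Genes of the response to unfolded protein in the endoplasmic reticulum rose. These list shifts were called by camera at a preset correlation. With the correlation estimated from the arrays 0 of 33 lists passed (smallest adjusted p = 0.139, 11 at an unadjusted p under 0.05), while fry called 19. That estimate was made without the replicate block, so variation shared by same-numbered arrays stayed in it. Cyp3a25, a drug-metabolising P450, showed the largest fall among named genes, from 12.23 ± 0.42 to 7.18 ± 0.48 (SD, n = 3 each), which is 33.1-fold. Cxcl10, a chemokine that attracts T cells, showed the largest rise, from 5.69 ± 0.43 to 10.58 ± 0.87, which is 29.6-fold.

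In all, 3037 rows (18.6%) changed, of which 1559 were higher and 1478 lower. Among named genes 2860 changed, 1478 higher and 1382 lower. A change of at least 1.5-fold was found in 1962 rows, 847 higher and 1115 lower. Of the 184 rows changed at least 4-fold, 32 were higher and 152 lower. The groups did not overlap in 35.1% of rows, against 10% by chance for 3 against 3 arrays that can be exchanged freely, a share that pairing of the arrays would change. With the replicate number as a block, 4686 rows changed, 2582 higher and 2104 lower, and all 3037 kept their call and sign. The count was 5190 with array weights, 1509 at an adjusted p under 0.01, 2022 without DMSO replicate 1, 1793 without DMSO replicate 2 and 1738 without CsA replicate 2.

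The 10 largest rises also included Nupr1, a stress-induced nuclear protein (3.99 ± 0.33, log2 difference ± SE, adjusted p = 0.000138), and Rsad2, an antiviral enzyme induced by interferon (3.87 ± 0.20, adjusted p = 2.69e-05). The others were Fam171b (3.50), the tyrosine phosphatase gene Ptpn14 (3.40), Gpr137b (3.29), Pate14 (3.26), the stress-responsive Ndrg1 (3.20), Lgals3, which encodes galectin-3 (3.12), and Csn3, which encodes kappa-casein (2.86). Pate14 began at 3.68 in DMSO and Plscr2, below, ended at 3.74 in CsA, both near the bottom of the scale, where RMA compresses differences. The 10 largest falls after Cyp3a25 were Sult1a1, a sulfotransferase (-4.33 ± 0.26, adjusted p = 3.60e-05), Cyp3a11 (-4.23 ± 0.22, adjusted p = 2.69e-05), Plscr2 (-4.14), the carboxylesterase Ces1d (-4.12), Cyp2c29 (-3.98), Baat (-3.90), the aldehyde dehydrogenases Aldh1a1 (-3.89) and Aldh1a7 (-3.87), and Cyp2f2 (-3.87).

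**Figure D2:**
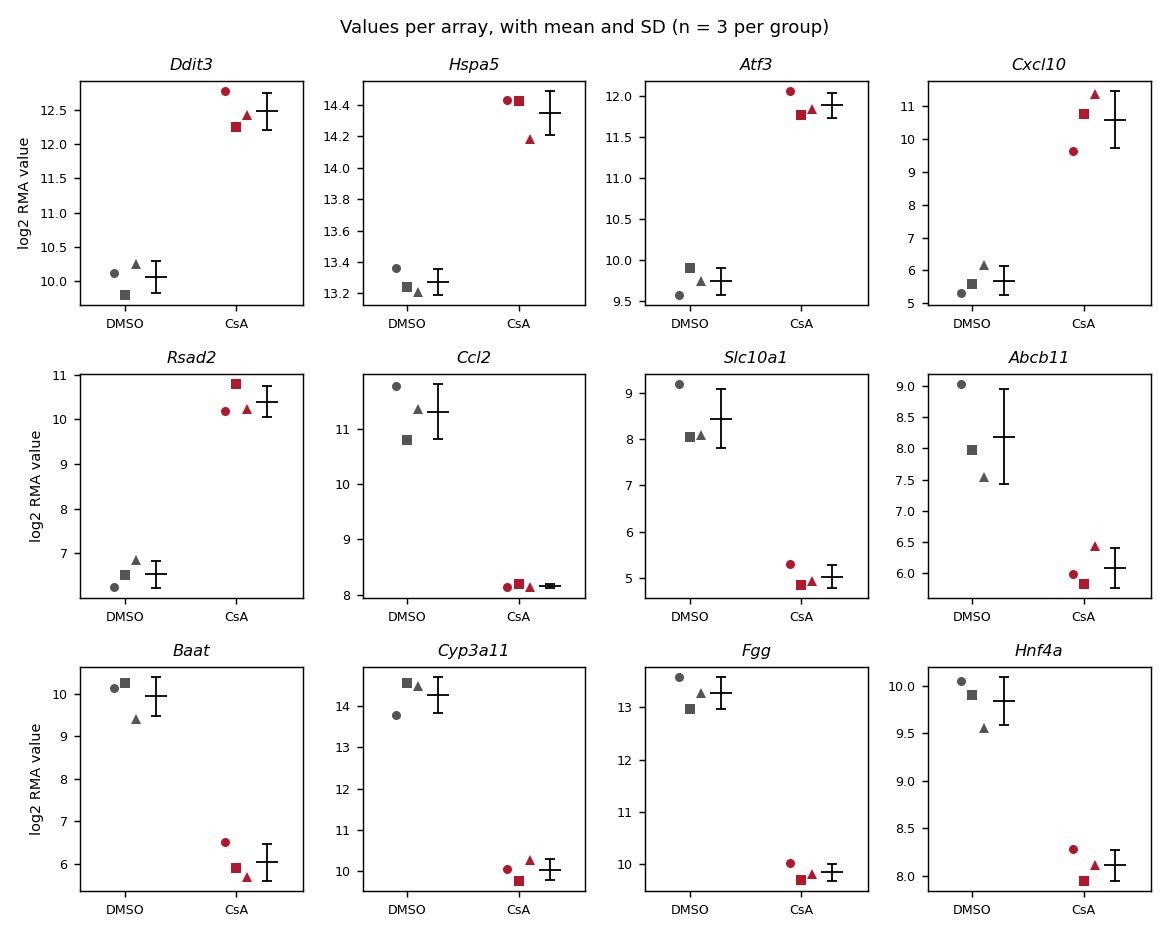
Log2 RMA values (y axis, not starting at 0) of 12 genes in each array, grey for DMSO and red for CsA, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean and SD (n = 3 per group). The groups do not overlap for any of the 12 genes, and Ddit3, Hspa5, Atf3, Cxcl10 and Rsad2 are higher with CsA while the other 7 are lower.

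Endoplasmic reticulum stress genes rose. In the unfolded protein response list 20 of 33 measured genes were higher, 0 lower and 13 did not pass, and 24 were higher adjusted over the list alone. The list's median difference was 0.74 (camera adjusted p = 6.19e-13, and adjusted p = 0.139 with an estimated correlation). Ddit3, which encodes the stress-induced transcription factor CHOP, rose 5.35-fold (2.42 ± 0.17), and Ppp1r15a, which encodes a phosphatase subunit that restores translation, rose 5.49-fold (2.46 ± 0.12). Atf3 rose by 2.15, Manf by 1.83 and the luminal chaperone gene Hspa5 by 1.07. In the ATF4 and amino acid response list 12 of 31 genes were higher, 2 lower and 17 did not pass. Adjusted over the list alone 14 were higher and 4 lower (median only 0.26, camera adjusted p = 0.00035, and adjusted p = 0.342 with an estimated correlation). Atf4, Ddit3 and Trib3, all higher, are in this list and in the unfolded protein response list, so the lists are not separate evidence. The amino acid transporter genes Slc7a1 and Slc3a2 rose by 1.04 and 1.45, and Trib3, a target of ATF4 and CHOP, by 1.30. For transport from the endoplasmic reticulum to the Golgi and protein translocation, 17 of 45 genes were higher and 2 lower, with 18 and 4 adjusted over the list alone and 4 lower with the replicate block (camera adjusted p = 0.000884, and adjusted p = 0.49 with an estimated correlation). Kdelr3, a receptor that returns resident proteins to the reticulum, rose by 0.92, the signal peptidase gene Spcs2 by 0.74, and Srpr and Srp68 of the signal recognition pathway by 0.68 and 0.58. The 17 became 9 without DMSO replicate 2 or CsA replicate 1 and 10 without CsA replicate 2, and the 2 lower became 0 in limma without DMSO replicate 2 or CsA replicate 2 and 1 without DMSO replicate 1, CsA replicate 1 or CsA replicate 3.

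Genes of bile acid handling fell. In the list of bile acid synthesis and conjugation 13 of 18 genes were lower, 0 higher and 5 did not pass, with 14 lower adjusted over the list alone. Its median difference was -1.12 (camera adjusted p = 9.47e-10, and adjusted p = 0.139 with an estimated correlation). Baat, which joins bile acids to amino acids, was 14.9-fold lower, Nr1h4, which encodes the bile acid receptor FXR, 5.77-fold, Cyp2c70 3.78-fold and Slc27a5 3.26-fold. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by -1.54 ± 0.47 with an adjusted p of 0.0518, and an adjusted p of 0.00876 with the replicate block. It also passed with a trended prior variance (adjusted p = 0.0498), with array weights (0.00175), with the dimmest 20% of rows left out (0.0471), without DMSO replicate 3 (0.00086) and without both arrays numbered 3 (0.00203). Among bile acid and drug transporters 11 of 22 were lower and 0 higher in limma, with 12 lower and 1 higher adjusted over the list alone, 1 higher with the replicate block and 2 higher without DMSO replicate 1 (camera adjusted p = 2.33e-06, and adjusted p = 0.329 with an estimated correlation). Slc10a1, which takes bile salts up from blood, went from 8.44 ± 0.64 to 5.03 ± 0.24 (SD, n = 3 each), 10.6-fold lower. Abcb11, the bile salt export pump, was 4.28-fold lower (-2.10 ± 0.34, adjusted p = 0.00336), and Abcb4, which exports phospholipid into bile, 3.28-fold (-1.71 ± 0.31, adjusted p = 0.00563). Slco1a4 (-2.40), Abcg5 (-1.66) and Abcb1a (-1.44) fell too. Abcc2, which exports conjugates into bile, differed by 0.29 ± 0.28 and did not pass (adjusted p = 0.557), and passed at 0.66 without DMSO replicate 1 (adjusted p = 0.0282).

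Drug-metabolising genes fell, and the cytochrome P450 list had the lowest median of the 34 lists. Of 30 genes in that list 23 were lower, 1 higher and 6 did not pass, with 24 lower and 1 higher adjusted over the list alone. Besides P450 genes the list was written with the reductase gene Por and the receptor genes Nr1i2, Nr1i3 and Ahr. Nr1i2, which fell, is also in the list of hepatocyte transcription factors and nuclear receptors. The median difference was -1.43 (camera adjusted p = 1.45e-15, and adjusted p = 0.139 with an estimated correlation). Cyp3a11 was 18.7-fold lower, Cyp2d9 6.60-fold and Cyp2c23 3.78-fold. Cyp2b10, induced by ligands of the receptor CAR, was at 11.96 ± 0.19 in DMSO and 11.99 ± 0.48 in CsA, a difference of 0.03 ± 0.22. In phase II conjugation 18 of 28 genes were lower and 0 higher, with 23 lower adjusted over the list alone (median -0.87, camera adjusted p = 8.76e-16, and adjusted p = 0.139 with an estimated correlation). The glucuronosyltransferase genes Ugt2b36 (-3.78), Ugt2b5 (-3.09) and Ugt2a3 (-2.48) fell.

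Lipid genes fell as well. For fatty acid oxidation and targets of the receptor PPARA, 25 of 35 genes were lower and 0 higher, with 29 lower and 1 higher adjusted over the list alone. The median was -1.30 (camera adjusted p = 1.07e-21, and adjusted p = 0.139 with an estimated correlation). Angptl4, an inhibitor of lipoprotein lipase (-2.75), Cyp4a10 (-2.74) and the thiolase genes Acaa1b (-3.09) and Acaa2 (-1.62) fell. In fatty acid and triglyceride synthesis 8 of 22 genes were lower and 1 higher, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.000309, and adjusted p = 0.404 with an estimated correlation). Fry gave that list an adjusted p of 0.057. Mttp (-1.67), Apob (-1.57) and Dgat2 (-1.20), which act in the assembly or filling of very low density lipoprotein, and Thrsp (-1.71) fell. In cholesterol synthesis 7 of 16 genes were lower (4 without DMSO replicate 2 or CsA replicate 2) and 0 higher, with 9 lower adjusted over the list alone (camera adjusted p = 2.89e-05, and adjusted p = 0.139 with an estimated correlation). The enzyme genes Hsd17b7 (-1.04), Nsdhl (-0.62), Tm7sf2 (-1.03) and Dhcr7 (-1.28) were among those that fell.

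Genes of secreted proteins fell. Among plasma proteins and coagulation factors 33 of 43 were lower, 2 higher and 8 did not pass, with 36 lower and 2 higher adjusted over the list alone (median -1.10, camera adjusted p = 5.04e-19, and adjusted p = 0.139 with an estimated correlation). Serpinf2, which encodes the plasmin inhibitor, fell 7.82-fold, Hrg 5.72-fold, vitronectin (Vtn) 4.34-fold and coagulation factor F12 2.72-fold. In the acute-phase and complement list 25 of 36 were lower and 1 higher (2 with the replicate block), with 27 and 1 adjusted over the list alone (median -1.17, camera adjusted p = 8.43e-16, and adjusted p = 0.139 with an estimated correlation). The fibrinogen chain genes Fgg, Fga and Fgb fell 10.8-fold, 8.12-fold and 5.33-fold, and the complement gene Cfb 3.60-fold. Albumin (Alb), near the top of the scale at 15.29 ± 0.01 in DMSO and 15.19 ± 0.05 in CsA, differed by -0.10 ± 0.10 and did not pass. Of the transcription factors and nuclear receptors of hepatocytes, 15 of 33 were lower and 0 higher in limma (3 with the replicate block), with 16 lower and 2 higher adjusted over the list alone (median -0.47, camera adjusted p = 1.96e-06, and adjusted p = 0.14 with an estimated correlation). Onecut1 fell 7.04-fold, Nr1i2, which encodes the xenobiotic receptor PXR, 3.60-fold, and Hnf4a, a master regulator of hepatocyte genes, 3.31-fold.

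In gluconeogenesis and glycolysis 13 of 22 genes were lower and 1 higher, with 15 and 2 adjusted over the list alone (median -0.79, camera adjusted p = 1.48e-07, and adjusted p = 0.139 with an estimated correlation). The glucose transporter gene Slc2a2 (-3.33), glycogen synthase Gys2 (-2.55), the glucose-6-phosphate transporter Slc37a4 (-2.30) and pyruvate kinase Pklr (-1.69) fell. In the urea cycle and amino acid breakdown 23 of 34 were lower and 2 higher, with 25 and 2 adjusted over the list alone (median -1.03, camera adjusted p = 4.18e-14, and adjusted p = 0.14 with an estimated correlation). Arginase (Arg1) fell 10.3-fold, Kmo 5.44-fold, the alanine aminotransferase Gpt 4.40-fold and Hgd 4.31-fold. Oxidative phosphorylation had 1 lower gene, Sdha (-0.44), 0 higher and 53 not passing among 54, with 0 adjusted over the list alone. With the replicate block 7 were lower and 1 higher, including Ndufa9 (-0.33, adjusted p = 0.0418), Uqcrc1 (-0.35, adjusted p = 0.0494) and Ndufa1 (0.31, adjusted p = 0.0379). The list's median was -0.075 (camera adjusted p = 0.0436, and adjusted p = 0.692 with an estimated correlation). The list's call was lost without DMSO replicate 2 (adjusted p = 0.0548), DMSO replicate 3 (0.14), CsA replicate 1 (0.0835) or CsA replicate 2 (0.201), after repeated quantile normalization (0.127) or centring (0.0775), with the dimmest 20% (0.0782) or 50% (0.06) of rows left out, and by fry (0.389). Sdha lost its call without DMSO replicate 1, DMSO replicate 2, CsA replicate 1 or CsA replicate 2 (differences from -0.47 to -0.40), and 2 genes were lower without CsA replicate 3.

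**Figure D3:**
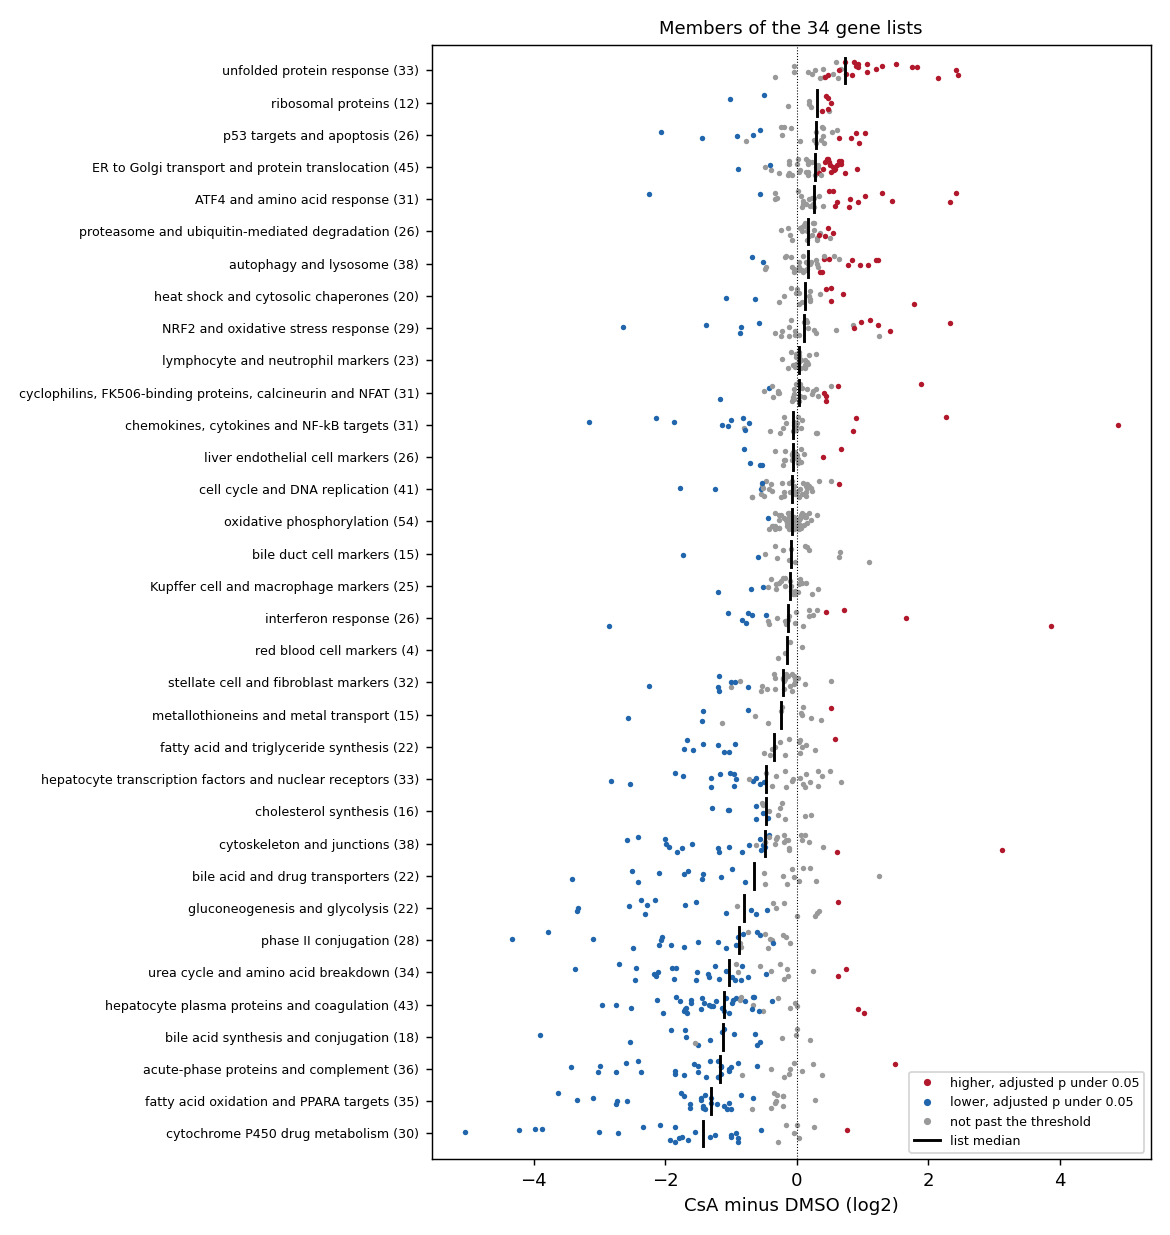
CsA minus DMSO differences (x axis, log2) of the measured members of each of the 34 gene lists (y axis, number of members in brackets), with 1 point per gene, red for higher and blue for lower at an adjusted p under 0.05, grey otherwise, and a black bar for the list median. List medians run from -1.43 for the cytochrome P450 list to 0.74 for the unfolded protein response.

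Protein turnover lists had small upward medians that level-matched random lists often reached. In the proteasome and ubiquitin list 4 of 26 genes were higher and 0 lower, with 6 higher adjusted over the list alone (median 0.18, camera adjusted p = 0.0077, and adjusted p = 0.548 with an estimated correlation). Fry gave it an adjusted p of 0.0629, and its median lay above that of only 82.3% of 10000 lists matched on mean level. The 4 became 8 with the replicate block, 1 without DMSO replicate 1, DMSO replicate 2 or CsA replicate 2, 2 without CsA replicate 3 and 7 without DMSO replicate 3. Psmc2, an ATPase subunit of the proteasome, rose by 0.55. In autophagy and lysosome 10 of 38 were higher and 2 lower (4 with the replicate block), with 11 and 4 adjusted over the list alone (median 0.17, camera adjusted p = 0.0113, and adjusted p = 0.357 with an estimated correlation). The list's call was lost without DMSO replicate 3 (adjusted p = 0.111) or CsA replicate 1 (adjusted p = 0.0695), and its median lay above 88.4% of the matched lists. The 10 became 5 without DMSO replicate 1, DMSO replicate 2, CsA replicate 1 or CsA replicate 2. The cargo receptor Sqstm1 rose by 1.24, the lysosomal enzyme Gla by 1.21, Gabarapl1 by 0.96 and Atg2a by 0.84.

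Other stress lists were mixed and not shifted by camera. Among heat shock and cytosolic chaperone genes 5 of 20 were higher and 2 lower, with 6 and 2 adjusted over the list alone (camera adjusted p = 0.19). Hspa1a rose by 1.79 and Hspb8 by 0.71, and the list passed without CsA replicate 3 (adjusted p = 0.0367). The 5 became 2 without DMSO replicate 1, DMSO replicate 2 or CsA replicate 2 and 3 without CsA replicate 1. In the NRF2 and oxidative stress list 6 of 29 were higher and 5 lower, with 7 and 5 adjusted over the list alone (camera adjusted p = 0.55). Srxn1 and Taldo1 rose by 1.43 and 1.11, Aox1 fell (-1.38), and Nqo1 differed by -0.33 ± 0.22 without passing. Among p53 targets and apoptosis genes 5 of 26 were higher and 5 lower, with 8 and 5 adjusted over the list alone, 12 higher with the replicate block, 8 higher without CsA replicate 3 and 3 lower without DMSO replicate 2 (camera adjusted p = 0.454). Gadd45a and Bcl2l11 rose by 0.95 and 0.91, while Gadd45b (-2.06) and Gadd45g (-1.44) fell. In cell cycle and DNA replication 1 of 41 was higher and 4 lower, with 1 and 3 adjusted over the list alone, 3 and 7 with the replicate block, 3 higher without DMSO replicate 3 and 2 lower without CsA replicate 1 (camera adjusted p = 0.0927). Rrm2 (-1.77) and Ccnd1 (-1.24) fell and Mcm7 rose by 0.64. That list passed without DMSO replicate 2 (adjusted p = 0.0107) and without both arrays numbered 3 (0.0361). Only 12 of 58 ribosomal protein genes were measured and named, 5 higher and 2 lower, with 6 and 2 adjusted over the list alone (camera adjusted p = 0.103). Rpl15 fell (-1.02), and the list passed upward on ranks (adjusted p = 0.0463) and by fry (0.0492). Of the 5 higher, 1 passed without CsA replicate 1 and 0 in limma without DMSO replicate 1, DMSO replicate 2 or CsA replicate 2.

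Cyclophilins, which bind CsA, were tested in 1 list with FK506-binding proteins, calcineurin and NFAT, and the list showed no common direction. In it 5 of 31 genes were higher and 2 lower, both adjusted over all rows and adjusted over the list alone (camera adjusted p = 0.647). With the replicate block 4 were lower, and the 5 higher became 2 without DMSO replicate 1, CsA replicate 1 or CsA replicate 2 and 3 without DMSO replicate 2. Fkbp11 and Fkbp2, of the endoplasmic reticulum, rose by 1.89 and 0.63, and Fkbp5, a target of the glucocorticoid receptor, fell (-1.17). Cyclophilin B (Ppib) differed by 0.25 ± 0.10 (adjusted p = 0.135, and 0.0445 with array weights). Rcan1, a calcineurin target, differed by -0.38 ± 0.20 (adjusted p = 0.236, and 0.0473 with the replicate block). For metallothioneins and metal transport 4 of 15 genes were lower and 1 higher (2 with the replicate block), with 5 and 2 adjusted over the list alone (median -0.24, camera adjusted p = 0.0157, and adjusted p = 0.344 with an estimated correlation). The members that fell act in iron, manganese and zinc handling: Hjv (-2.57), Slc30a10 (-1.44), Tfr2 (-1.42) and Slc39a14 (-0.74). The call was lost on ranks (adjusted p = 0.06) and with the dimmest 50% of rows left out (adjusted p = 0.081).

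Inflammatory genes moved in both directions. In the list of chemokines, cytokines and NF-kB targets 9 of 31 genes were lower and 4 higher, with 10 and 5 adjusted over the list alone (median -0.058, camera adjusted p = 0.0142, and adjusted p = 0.537 with an estimated correlation). Fry gave it an adjusted p of 0.108, and 4.03% of the lists matched on mean level lay at or below its median. The monocyte chemokine Ccl2 fell 8.89-fold, from 11.31 ± 0.49 to 8.16 ± 0.03 (SD, n = 3 each), and the adhesion molecule Icam1 3.64-fold. Ccl5 rose 4.82-fold, beside the rise of Cxcl10. In the interferon response list 4 of 26 were higher and 7 lower, with 5 and 8 adjusted over the list alone (camera adjusted p = 0.172). The 4 became 2 without DMSO replicate 2 or CsA replicate 2, and the 7 became 3 without DMSO replicate 2 and 4 without DMSO replicate 1 or CsA replicate 1. Rsad2 and Oasl1 rose 14.6-fold and 3.16-fold, while the guanosine triphosphatase genes Iigp1 and Irgm1 fell 7.24-fold and 1.70-fold.

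Cell contact and cytoskeleton genes fell. In the cytoskeleton and junctions list 18 of 38 were lower (11 without CsA replicate 1) and 2 higher, with 21 and 2 adjusted over the list alone (median -0.48, camera adjusted p = 6.74e-09, and adjusted p = 0.139 with an estimated correlation). The gap junction genes Gjb1 and Gjb2 fell 5.96-fold and 3.84-fold, E-cadherin (Cdh1) 3.34-fold and the tropomyosin gene Tpm2 4.01-fold.

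Most markers of other cell types did not pass, and more of those that passed were lower than higher. Stellate cell and fibroblast markers were lower for 7 of 32 genes and higher for 0, with 8 lower adjusted over the list alone (median -0.21, camera adjusted p = 5.14e-05, and adjusted p = 0.273 with an estimated correlation). The 7 became 12 with the replicate block, which also called 1 higher, 3 without CsA replicate 1 and 2 without CsA replicate 2. Ccn2 (-2.24) and the collagen gene Col4a1 (-1.18) fell. Kupffer cell and macrophage markers were lower for 3 of 25 genes and higher for 0, and 3 were lower adjusted over the list alone (median -0.10, camera adjusted p = 0.0436, and adjusted p = 0.548 with an estimated correlation). The 3 became 1 without DMSO replicate 1, CsA replicate 1 or CsA replicate 2, when Fcer1g and Vsig4 lost their calls, and the block called 1 higher. Mpeg1 fell (-1.20). That list's call was lost without DMSO replicate 1 (adjusted p = 0.3) or CsA replicate 1 (adjusted p = 0.102), with an adjusted p of 0.0577 after repeated quantile normalization and 0.228 by fry. Liver endothelial markers had 2 higher and 4 lower genes of 26, the same numbers adjusted over the list alone (camera adjusted p = 0.106), with Egfl7 at -0.80. They passed on ranks (adjusted p = 0.0474), without DMSO replicate 2 (adjusted p = 0.014) and without CsA replicate 3 (adjusted p = 0.0367). The 4 became 2 without DMSO replicate 1, DMSO replicate 3, CsA replicate 1 or CsA replicate 3 and 1 without CsA replicate 2. The 2 higher, Oit3 (0.67) and Esam (0.40), became 1 without DMSO replicate 1, DMSO replicate 2 or CsA replicate 1 and 0 in limma without CsA replicate 2. Bile duct markers had 0 higher and 2 lower of 15, with 1 and 3 adjusted over the list alone (camera adjusted p = 0.239), and Pkhd1 fell (-1.73). With the replicate block 2 were higher, Prom1 among them (1.11, adjusted p = 0.0329), as were 3 without CsA replicate 3 and 1 without DMSO replicate 2, and 1 was lower without DMSO replicate 1 or CsA replicate 1. Lymphocyte and neutrophil markers had 0 changed genes of 23 in limma, also adjusted over the list alone (camera adjusted p = 0.598). Of the red blood cell markers 4 were measured, too few for the list test, and 0 changed, also adjusted over the list alone.

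By camera at its preset correlation 23 of 33 lists shifted, 5 up and 18 down, and 23 with the replicate block. With an estimated correlation, run without the block, 0 did. Against 10000 lists matched on mean level, 3 of the 23 medians, those for proteasome, autophagy and chemokines, were not beyond all but 2.5% of them. Of the lists not shifted by camera, the medians for interferon response (1.1% at or below), cell cycle (1.58%) and p53 targets (99.41%) were. Both arrays numbered 3 stood apart on the second component. With both left out, an alternative chosen after seeing the data, 4161 rows changed and 24 lists shifted.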

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

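Leaving out both arrays numbered 3 was chosen after seeing the data, and the other alternatives were fixed before. The number of changed rows, 3037, became 4686 with the replicate block, 5190 with array weights, 1509 at an adjusted p under 0.01 and 1738 to 3219 when 1 array was left out (2022 without DMSO replicate 1, 1793 without DMSO replicate 2, 2094 without CsA replicate 1). The number higher, 1559, became 2582 with the block, 2927 with array weights, 627 at 0.01 and 764 to 1697 with 1 array left out (884 without DMSO replicate 1, 764 without DMSO replicate 2 and also without CsA replicate 2, 975 without CsA replicate 1). The number lower, 1478, became 2263 with array weights, 882 at 0.01 and 974 to 1522 with 1 array left out, with 974 without CsA replicate 2. A stricter threshold lowers counts by construction, and otherwise the cause was not tested. The 1962 rows changed at least 1.5-fold stayed within 1.5 times in every alternative (1419 to 2377). With both arrays numbered 3 left out 4161 rows changed, of which 2855 were among the 3037. Centring of the arrays put 61.0% of changed rows on the higher side, against 51.3%, and moved the median of all rows from 0.035 to 0.087.

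The count of 23 shifted lists became 0 with an estimated correlation (camera, 11 at an unadjusted p under 0.05) and lay between 19 and 25 elsewhere. Of the 23 lists, 16 kept their call and sign in every other alternative in which they were tested. The robust prior variance, array weights and the threshold of 0.01 were not run on lists. The estimated correlation was not run with the replicate block. With the dimmest 50% of rows left out, some lists had too few members for the test. Of the 157 genes named by the rule 136 passed, and 117 of these kept their call and sign in every alternative that held them. The other 19 lost the call with at least 1 array left out and kept their sign. Genes among the dimmest rows had no value in the filtered fits, and the threshold of 0.01 was not applied to these counts. Counts within single lists moved by up to 11 members with 1 array left out (plasma proteins from 33 to 22 lower without CsA replicate 2), and list counts of 0 to 2 by up to 3. The block ended no call and brought 8 more named genes past the threshold. Values that changed sign did not pass the threshold (the highest or lowest given is with 1 array left out): Cyp2b10 from 0.03 to -0.077 without DMSO replicate 1 and -0.24 without CsA replicate 1 (0.19 at the highest), and medians of the lists for NRF2 (-0.017 without both arrays numbered 3), cyclophilins (-0.011 and -0.017 without DMSO or CsA replicate 2, 0.049 at the highest), cell cycle (0.0096 with the dimmest 50% of rows left out, 0.071 without DMSO replicate 1, -0.15 at the lowest), interferon (0.00075 without DMSO replicate 3, -0.25 at the lowest), endothelial cells (0.0034 without DMSO replicate 3, 0.012 without CsA replicate 1, -0.13 at the lowest), bile duct cells (0.030 and 0.022 without the same arrays, -0.129 at the lowest) and lymphocytes (-0.0088 without CsA replicate 3, 0.095 at the highest). The cause was not tested.

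The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only the real one, 1 of the 10, gave 3037 changed, 1559 higher, 1478 lower or 1962 changed at least 1.5-fold, and the highest of the others was 0 in limma. Every other split put CsA and DMSO arrays in both groups, which moved the treatment difference into the spread within groups. Few calls were therefore to be expected from them. At an unadjusted p under 0.05 the real split gave 5098 rows, against at most 236 in the 3 others that part all 3 pairs and 1187 in the 6 that part 1 pair. For lists, 2 of the 10 gave at least 23. The highest other, with 24, exchanged the groups of the arrays numbered 3, and the other 8 gave 10 to 18, so camera at its preset correlation called lists in splits with 0 changed rows. These splits held unequal numbers of CsA arrays on their sides, so part of the CsA difference stayed between them. The block gave 23. Signal over background was not measured here, so no limit on dim rows can be set beyond the filters.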

Other observations

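The tests of a lower hepatocyte share, of secreted messages, of stellate cells and of macrophages or lymphocytes were chosen only after the result was seen. The genes in the next paragraph were chosen after their values were seen, as a pick from the 25 largest differences in each direction outside the lists among genes whose groups did not overlap.

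Outside the lists, lower genes were the carboxylesterase Ces1f (-3.72, log2 difference, n = 3 per group), the antimicrobial peptide gene Leap2 (-3.60), Lrg1 (-3.26), the mitochondrial carrier Slc25a47 (-3.24), the retinol dehydrogenase Rdh7 (-3.19), the steroid dehydrogenase Hsd17b2 (-2.91) and the asialoglycoprotein receptor subunit Asgr1 (-2.54). Plat, which encodes tissue plasminogen activator (-3.16), Bicc1 (-3.08), Lhfp (-2.89), Akap12 (-2.78) and Cavin2 (-2.73) fell as well. No theme of these genes was tested. On the higher side stood Armcx1 (2.76), Slc43a3 (2.64), the phosphomannomutase Pmm1 (2.59), the transcription factor Insm1 (2.53), the epithelial splicing regulator Esrp1 (2.46), Bex2 (2.30), the lysosomal glycoprotein Gpnmb (2.13), Fosl1 (1.87) and Klf4 (1.85). Insm1 began at 3.63 in DMSO, near the bottom of the scale.

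The hepatocyte lists fell together, with a median of -1.10 over the members of 9 lists, which the written prediction counted but did not name. A lower share of hepatocytes would raise the markers of any other cell type present. The median of 124 such markers was -0.065, with 2 higher and 16 lower. Only 13 of them lay above the median level of all rows. These had a median of -0.72 (SD over members 0.92), with 0 higher in limma and 8 lower. The 3 bile duct markers among them were higher without passing, of which Cd24a and Prom1 passed with the replicate block. Which cells these messages came from was not measured, and the brightest, Ccn2 (12.79 in DMSO), could stem from hepatocytes themselves. The markers run against a lower share only if they stand for other cells. A bias against abundant rows was argued against by lists matched on mean level. All 9 lists, and all 10 when hepatocyte transcription factors are counted, lay below all but 2.5% of 10000 such lists. The 9 were named after the list results had been computed, so their count was not a blind test. Faster loss of messages for secreted proteins alone would spare the other hepatocyte lists, whose median was -1.07. The secreted lists lay only -0.081 from them (SD over pairs 0.105). Those other lists hold membrane proteins too, such as transporters and P450s, and a joint loss of messages for secreted and membrane proteins was not tested as such. Such a loss alone would spare a list made mostly of other enzymes. The urea cycle and amino acid breakdown list is mostly of that kind. Its median of -1.03 (-1.38, -1.27 and -0.64 in the numbered pairs), with 23 of 34 genes lower and 2 higher, argues against it for that list. A change of transcription or of message stability within the hepatocytes may remain as a hypothesis, and no measurement here separates these or dying cells.

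The 11 contractile genes that drew attention, such as Acta1 (-2.19), Cnn1 (-1.98), Tpm2 (-2.01) and Ankrd1 (-2.03), had a median of -1.98, but were picked because they fell, so it says nothing of contractile genes as a group. Of MRTF and SRF targets not yet looked at, 14 were measured, with a median of -0.53 and 6 lower, among them Cnn2 (-1.58), Mylk (-1.28) and Myh9 (-1.01), which makes a fall of that program a candidate explanation. YAP and TEAD targets not yet looked at had a median of -0.29, just short of the bound of -0.3 set for them, with 6 of 17 lower, and stay open. Fewer stellate cells or fibroblasts cannot be told apart from these: of 4 stellate markers above the median level, all lower, Tagln and Ccn2 are among the 11 picked genes, and the median of -1.06 over the other 2, Col4a1 and Col4a2, met its bound on fewer genes than the minimum of 5 set for a list. Col4a2 (-0.94) lost its call without DMSO replicate 2 (-0.97, adjusted p = 0.0568) or CsA replicate 2 (-0.89, adjusted p = 0.0707), with a difference about as large.

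Cxcl10, Rsad2 and Ccl5 rose while Ccl2 and Cxcl1 fell. A general interferon response is argued against by 14 interferon-stimulated genes not yet looked at, whose median was -0.47 with 0 higher and 6 lower, such as Lgals3bp (-1.27) and Parp9 (-1.01). A general fall of NF-kB targets is argued against by 17 of them not yet looked at, with a median of -0.028, 2 higher and 4 lower, where Tnip1 rose by 0.94 and Sdc4 fell (-0.93). No level filter was applied to these 17. Some lay near the bottom of the scale in DMSO, such as Clec4e (3.25) and Ccl3 (3.94), where a fall could hardly show. More macrophages or lymphocytes cannot be told apart from a change within the hepatocytes: 48 of their markers had a median of -0.012 with 0 higher in limma and 3 lower, but only 3 lay above the median level of all rows, under the minimum of 5, although these (Slc40a1 -0.43, Fcer1g -0.51, Mpeg1 -1.20) run against it. Slc40a1 did not pass in limma (adjusted p = 0.118) and passed with the replicate block (adjusted p = 0.0364). An induction of Cxcl10, Rsad2 and Ccl5 within the hepatocytes may be 1 hypothesis among those left open, and its route was not tested.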
